A study of Rattus norvegicus with 3 samples.

How the data were processed

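The samples were single-cell suspensions of rat corpus cavernosum, 1 library from the nerve-injured group (CNIED) and 2 from the control group (CON). Per the series' design text, a clamp was closed on the cavernous nerve of both sides for 1 min at 5 mm from the major pelvic ganglion in CNIED rats, and control rats had the surgery without compression. Per the labels' protocols, tissue was digested with collagenases, protease and DNase for 40 min at 37 °C, and dead cells were removed with magnetic beads. Warm digestion can induce immediate early genes, and both steps can set the share of each cell type. The deposited values are raw UMI counts per gene and cell, 1 table per library, checked to be whole numbers. The labels' protocols name the Rhapsody platform for the libraries, while the submitters' processing notes name Cell Ranger 3.1.0, software for another platform, and genome build rn7; how these were combined, the annotation and the authors' filters on cells are not given in the sources used here. Every deposited cell held at least 501 detected genes and between 1002 and 7998 UMIs, so cells had been limited on depth before deposit. No genome of that build was used, and no coordinates are given.

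Cells with at least 300 genes and at most 20% mitochondrial UMIs were kept, which left 24194, 21683 and 14883 cells in CNIED and CON replicates 1 and 2. Scrublet called 0, 1 and 0 doublets, so it did not work here and doublets remain in the data. Cells were normalised to 10000 counts and clustered together without batch correction (scanpy 1.11.5, 2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1 with igraph 0.11.9, Python 3.11.15). Clusters were called X-like from markers of 22 cell types fixed before the data were examined, of which 210 of 217 were matched. A marker counted for a cluster when at least 20% of its cells held a UMI and its mean was at least 10% of the highest cluster mean, and the class with the largest share of its markers counted was taken. The scoring rule was changed 3 times after the clusters were seen and before any gene was tested: a first score called stromal clusters chondrocyte-like though Acan, Col2a1 and Hapln1 were near 0, and later ones left a cluster led by smooth muscle genes unnamed. In the last, classes whose shares lay within 0.1 of each other were told apart by the number of their markers among the 10 leading genes of the cluster, and clusters whose leading genes held more markers of another class stayed unnamed, as did those with under 3 markers counted or with classes that scored alike. This kept clusters 0, 1 and 5, whose best score was for fibroblast markers, out of the fibroblast-like class.

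Shares are percents of kept cells with exact Clopper-Pearson 95% intervals, computed from the deposited counts. Levels within a class are given as CPM as edgeR computes them, the summed count of a gene relative to the TMM-scaled total of its class in a library; haemoglobin totals are relative to the unscaled total. Counts were summed per library and class for the 7 classes with at least 50 cells in each library, and tested with edgeR 4.0.16 (quasi-likelihood, TMM, filterByExpr, Benjamini-Hochberg within class, threshold 0.05) in R 4.3.3. The smallest library of a class held from 322 lymphatic endothelial-like to 6801 fibroblast-like cells. Gene lists, 27 in number with 565 of 572 entries matched, 6 of them by another symbol in a RefSeq table of assembly GRCr8, were tested with camera of limma 3.58.1 (preset correlation 0.01) where at least 5 members were tested, and again with an estimated correlation. DESeq2 1.42.0 was an alternative. Tests were checked on simulated counts with 200 changed genes in each of 5 draws. The changed genes had at least 50 CPM, and a gene had the same dispersion in each library. Of 100 genes changed 2-fold, 48 to 79 were recovered in endothelial-like, 3 to 26 in fibroblast-like and 0 to 31 in macrophage-like cells. Up to 48 unchanged genes were called in a draw, in macrophage-like cells among 177 calls. The share of false calls could thus exceed the threshold of 0.05. A first version of that simulation recovered none of the changed genes in macrophage-like cells and was replaced by draws with a dispersion per gene.

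Named genes were, in the 3 classes with the most cells in their smallest library, the 10 called genes with the largest log2 fold each way, and 4 each way in other classes. They needed at least 50 CPM in the higher group, at least 1.5-fold in the same direction against each CON library and a gene symbol. Haemoglobin, ribosomal protein and mitochondrial genes and markers of another class were left out, and free places were filled by the genes with the largest fold that were not called. Up to 4 members of each list were named per class by lowest p, with Nos3, Pde5a and Gucy1a1 in endothelial-like, smooth muscle-like and pericyte-like cells whatever their values; Prkg1, fixed with them, was not matched. Some genes and 1 gene list, which enter the totals, are not reported here. Alternatives planned in advance were other cell filters, doublets kept, resolutions 0.5 and 2, libraries clustered alone, DESeq2 size factors, the DESeq2 test, no count filter, equal cells or totals per library, an estimated correlation, and leaving out each CON library. Chosen after the data were seen were the removal of the 6% of cells with the highest doublet scores, equal cells per cluster, the splits with a CON library alone, tests of clusters by number, and the level of a gene in a class as a percent of its level over all kept cells.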

Results

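Single-cell RNA sequencing was carried out on corpus cavernosum, the erectile tissue of the penis, from rats whose cavernous nerves had been crushed and from control rats. The cavernous nerves carry the signals for erection, and the injured group is named for the erectile dysfunction that follows (CNIED). CNIED was 1 library and the control group (CON) 2 libraries, all from tissue taken 4 weeks after surgery. The CNIED rats had been screened with apomorphine at 100 μg/kg, so they are a selected group. The deposited tables held 24943 cells and 87702675 unique molecular identifiers (UMIs) for CNIED, 22356 cells and 83224103 UMIs for CON replicate 1, and 15546 cells and 59063128 UMIs for CON replicate 2. The median cell held 3245, 3413 and 3458.5 UMIs in that order. Nothing in the labels says that the CON libraries came from separate animals, so p-values here measure the spread between these libraries, which may be technical. With 1 CNIED library, its spread is assumed to equal that of CON, and tests rest on 1 residual degree of freedom. The gene tests also share spread across the genes of a class. This added 5.84 degrees of freedom in fibroblast-like cells, the fewest, and 15.1 in Schwann-like cells, the most. Classes thus differ in how far their calls rest on shared spread.

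The first comparison asks whether the cellular makeup of the tissue differed after nerve injury. Endothelial and lymphatic endothelial-like cells took a smaller share of the CNIED library than of either CON library, and the stromal clusters together took a larger one. Endothelial-like cells, which line the blood spaces, were 5.65% of kept cells in CNIED (exact Clopper-Pearson 95% interval 5.36 to 5.95) against 13.3% and 11.5% in CON replicates 1 and 2, a ratio of 0.456 to the mean of CON. Pericyte-like cells, which wrap small vessels, were 2.86% against 7.27% and 6.84%, but 3.36% against 2.86% and 6.49% when each library was clustered alone. Lymphatic endothelial-like cells were 1.33% against 3.61% and 3.9%. All stromal clusters together made up 81.1% of CNIED against 57.5% and 63.7% of CON, a ratio of 1.34. Among them, clusters 0, 1 and 5 together made up 46.1% of CNIED (interval 45.4 to 46.7) against 21.3% and 18% of CON, a ratio of 2.34. With each library clustered alone, the stromal clusters kept out of the fibroblast-like class by the same rule were 17.2% of CNIED against 17.7% and 19.6% of CON (ratio 0.923), and all stromal clusters 80.8% of CNIED against 58.2% and 64.1% of CON.

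Macrophage-like cells were 1.62% of CNIED against 4.23% and 2.62% of CON, and smooth muscle-like cells 5.37% against 10.5% and 6.26%. Schwann-like cells, the glia of peripheral nerve, were 1.66% against 2.06% and 3.54%. Fibroblast-like cells outside clusters 0, 1 and 5 were 35.1% against 36.2% and 45.7%. In smooth muscle-like, Schwann-like, macrophage-like and fibroblast-like cells the higher CON share was 1.67, 1.72, 1.62 and 1.26 times the lower one. Clusters 0, 1 and 5 carried fibroblast markers but had more markers of another class among their leading genes, which include the cartilage genes Chad, Sox9 and Comp, so a naming rule set after the clusters were seen kept them out of the fibroblast-like class. Igsf10 and Grem1, leading genes of cluster 5, themselves differed between the groups, and its size was not recounted without them. Among cells outside the stromal clusters, endothelial-like cells were 29.9% of CNIED against 31.3% and 31.6% of CON, and smooth muscle-like cells 28.5% against 24.7% and 17.3%. Intervals cover counting error only, digestion and dead-cell removal before capture can set shares, and 1 library against 2 allows 3 splits and no exact permutation p below 0.333, so shares were not tested. The ratio for fibroblast-like cells was 0.856, but 1.49 when each library was clustered alone and 1.08 at resolution 0.5.

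**Figure D1:**
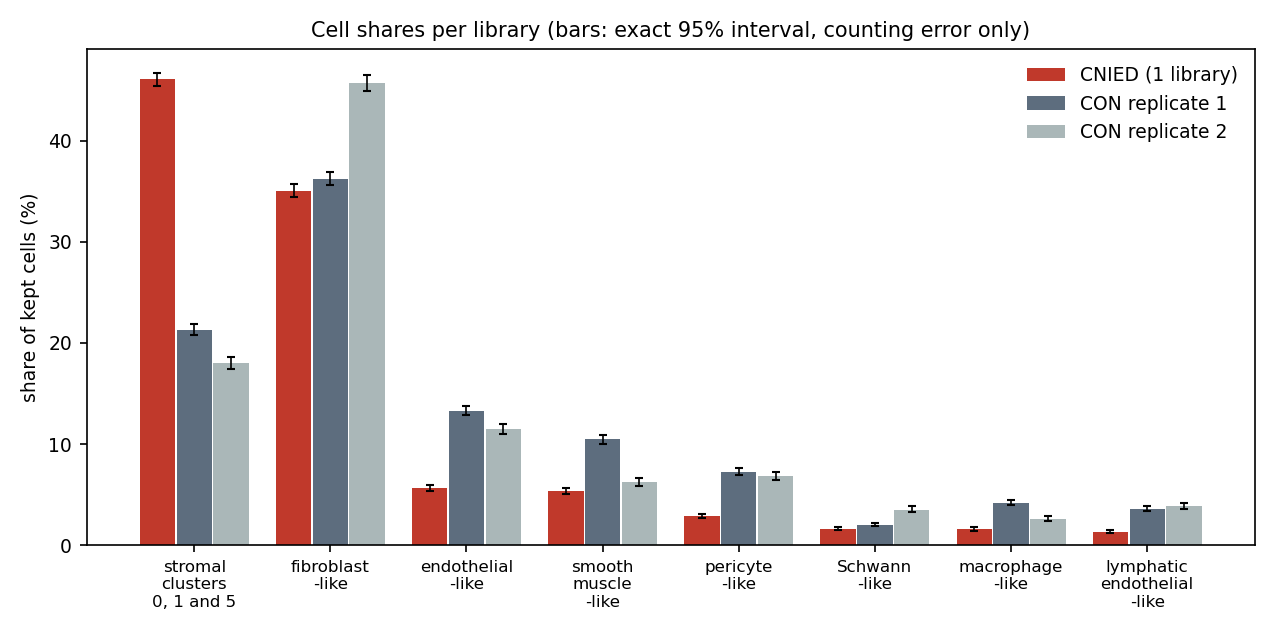
Share of kept cells (%, vertical axis) in 3 stromal clusters summed and in each cell class, 1 bar per library, with exact 95% binomial intervals for counting error. Clusters 0, 1 and 5 stand at 46.1% in CNIED against 21.3% and 18% in CON.

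The second comparison asks which genes differed within a cell class, from counts summed per library and class (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment within each class). In endothelial-like cells 87 of 12529 tested genes were called, 30 higher and 57 lower in CNIED. Schwann-like cells had 54 (27 higher and 27 lower), smooth muscle-like cells 41 (14 and 27), pericyte-like cells 14 (8 and 6), fibroblast-like cells 7 (3 and 4) and lymphatic endothelial-like cells 3 (3 and 0). In macrophage-like cells the edgeR test called 0, with 787 genes at an unadjusted p under 0.05, and DESeq2 called 2. The classes together gave 206 calls, against 97 when CON replicate 1 was set alone against the other libraries and 46 when CON replicate 2 was. In lymphatic endothelial-like cells those splits gave 67 and 20 calls, more than the real split, and in macrophage-like cells too both gave more calls than the real split. Counts moved widely with the processing, and so did their order between classes, from 1 to 452 in endothelial-like cells. With DESeq2 size factors the endothelial-like count was 6 (4 higher and 2 lower), the Schwann-like count 56 and the pericyte-like count 9 (4 and 5).

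Of 177 tests of fixed gene lists in the classes (limma camera, preset correlation), 56 were called, 18 higher and 38 lower in CNIED. With an estimated correlation 0 were called, and the camera adjusted p of each list called at the preset correlation was 0.919. That version of the test rests on the 1 residual degree of freedom, and over 177 tests it could hardly call a list. Its adjusted p of 0.919, given for lists below, thus cannot tell whether correlation between genes accounts for a call. Setting CON replicate 1 alone called 57 lists and setting CON replicate 2 alone called 49, which are similar numbers. In these splits CNIED stood with the other CON library, so they are not free of the group. A call in them thus cannot tell a difference of CNIED from a difference between the CON libraries. In 36 of the 56 the median of CNIED lay farther from both CON libraries than these lay from each other, and 10 of these were not called when a CON library was set alone. Of the 56, 45 were also called with a CON library alone, a limit named below for some lists only. With replicate 1 these include inflammatory cytokines and adhesion in fibroblast-like, smooth muscle-like and lymphatic endothelial-like cells and matrix proteases in fibroblast-like cells. With replicate 2 they include TGF-beta signalling in smooth muscle-like, fibrillar collagen in fibroblast-like and class II genes in pericyte-like cells.

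**Figure D2:**
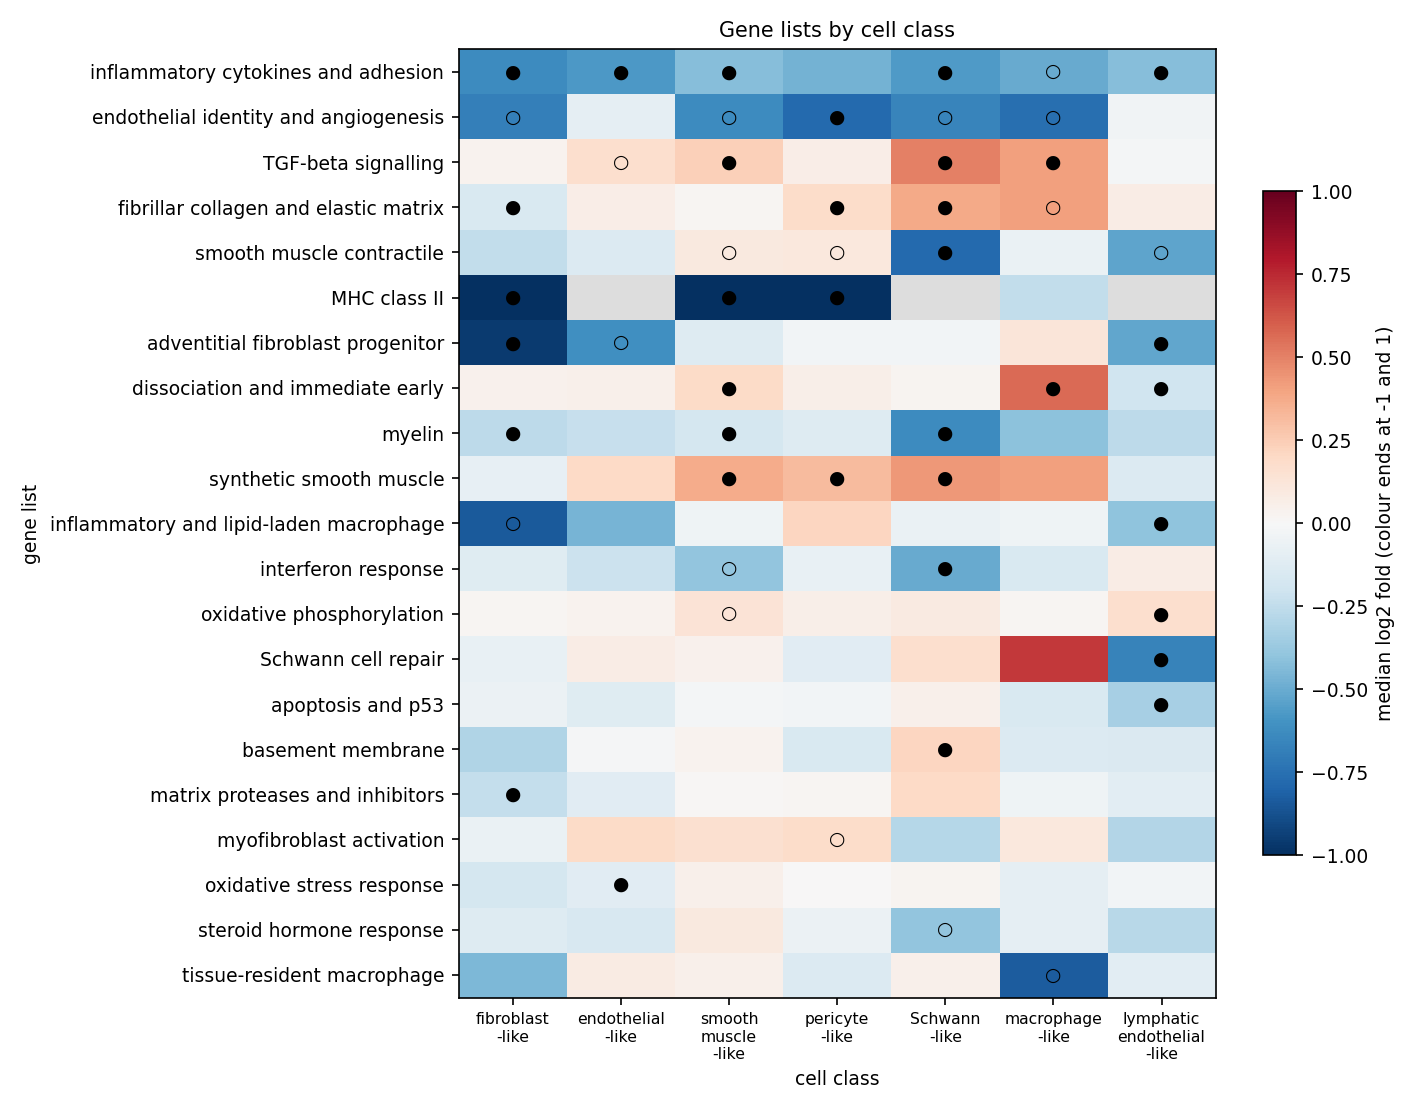
Median log2 fold of each gene list called in at least 1 class (vertical axis) in each cell class (horizontal axis), CNIED against CON, as colour; circles mark 52 called tests, filled circles the 35 of them in which CNIED lay beyond the distance between the CON libraries, and grey the lists not tested. Inflammatory cytokines and adhesion are lower in CNIED in each class in which that list was called.

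In fibroblast-like cells, Pi16 and genes of adventitial progenitors and inflammatory mediators were lower in CNIED. The median fibroblast-like cell held 2971.5 UMIs in CNIED against 3713.5 and 3803 in CON. Pi16, a marker of adventitial fibroblasts, fell by 2.30 on the log2 scale (SE 0.15, edgeR adjusted p = 0.00748), from 475 and 494 CPM in CON to 98.1. With equal cells per library 0 of the 7 calls in fibroblast-like cells held, and Pi16 had a log2 fold of -2.42 at an edgeR adjusted p of 0.605, while under the other settings its call held. Of 14 tested genes of adventitial progenitors 13 were lower, 1 past the test over all genes and 10 adjusted over the list alone (median log2 fold -0.96, or -1.22 and -0.63 against CON replicates 1 and 2, camera adjusted p = 1.83e-16). The adjusted p was 0.919 with an estimated correlation, and the list was also called when CON replicate 1 was set alone. Wnt2, a secreted signal, was 3.54 CPM against 12 and 10.5, and Cd55, an inhibitor of complement, 20.2 against 60.2 and 85.3 (edgeR adjusted p = 0.0786), neither called. Pi16 leads cluster 4, the largest part of the class in CON, which was 8.81% of it in CNIED against 21.2% and 21.5%. Cluster 2, the largest part in CNIED, was 25.3% against 11.6% and 14.6%. Within cluster 4 Pi16 was 683 CPM against 1681 and 1744. The other called genes with a symbol, chosen after their values were seen, were Gap43, lower at a log2 fold of -2.18, and Krt5, a keratin of basal epithelium at 4.74 CPM in CNIED and listed at 0 in both CON libraries.

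Inflammatory cytokines and adhesion genes were lower in 26 of 28 members in fibroblast-like cells, 0 past the test over all genes and 9 adjusted over the list alone (median log2 fold -0.63, or -0.65 and -0.37 against CON replicates 1 and 2, camera adjusted p = 4.51e-10, and 0.919 as adjusted p with an estimated correlation). The median member stood at 80.2% of its level over all kept cells, with 8 members under 20%. Endothelial markers in the class summed to 90.1 CPM of the unscaled total against 228 and 130. Il6, an inflammatory cytokine, was 228 CPM against 427 and 363, and Cxcl1, which attracts neutrophils, 1401 against 2529.9 and 2202, neither called. Fibrillar collagen and elastic matrix genes were lower in 20 of 24 members, 0 past the test over all genes and 3 adjusted over the list alone (median -0.15, camera adjusted p = 0.00145), with an adjusted p of 0.919 with an estimated correlation. Col3a1, a fibrillar collagen, was 4792 against 7192 and 9213 and was not called. Matrix proteases and inhibitors were lower in 13 of 20 members, 4 of them adjusted over the list alone (median -0.24, camera adjusted p = 0.000129, and 0.919 as adjusted p with an estimated correlation). Plau, the urokinase plasminogen activator, was 1659 CPM against 3705 and 3590.3 (edgeR adjusted p = 0.0613), Postn 83.5 against 221 and 211 (edgeR adjusted p = 0.0537), and Ptx3 32.5 against 122 and 94.8 (edgeR adjusted p = 0.0609), none of them called. Mme, a membrane peptidase, was 301 against 125 and 111 (edgeR adjusted p = 0.0537), and Tgfbi, an extracellular protein induced by TGF-beta, 1075 against 589.8 and 638 (edgeR adjusted p = 0.144), neither called.

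In endothelial-like cells of CNIED, Gpm6a, Ncam1 and Igfbp3 were higher, and Csf3, Birc3 and the list of inflammatory cytokines and adhesion were lower. Gpm6a, a membrane glycoprotein, rose from 14.8 and 20.8 CPM in CON to 64.8 (log2 fold 1.89, SE 0.21, edgeR adjusted p = 0.00261), and Ncam1, a cell adhesion molecule, from 29.9 and 24.7 to 77.4. Igfbp3, which binds insulin-like growth factors, rose from 281 and 219.6 to 594 (log2 fold 1.24, edgeR adjusted p = 0.0114). Csf3, the granulocyte growth factor G-CSF, fell by 2.23 on the log2 scale (SE 0.30, edgeR adjusted p = 0.00694), from 53.9 and 89 CPM to 15.1. Birc3, an inhibitor of apoptosis, fell by 1.30 (edgeR adjusted p = 0.00854). Under DESeq2 size factors Gpm6a and Ncam1 kept the call, and the edgeR adjusted p was 0.0736 for Igfbp3 and 0.0613 for Birc3, while Csf3 also lost the call. All 5 genes lost the call with no cell filter, with each library clustered alone and with the highest doublet scores removed.

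Nsg1, H1f0, a linker histone, and Sdc2, a heparan sulfate proteoglycan, were higher in endothelial-like cells at log2 folds of 1.18, 1.13 and 1.08, the last at 26.4% of its level over all kept cells. Pthlh and Efemp1, at 1.23 and 1.17, are leading genes of cluster 13, which was 28.4% of the class in CNIED against 17.4% and 9.13% in CON. Chodl and Myoc, at 1.49 and 1.22, stood in this class at 12.9% and 12.3% of their level over all kept cells, where they were higher in CNIED by 1.28 and 1.44. Lower genes were Rpgr (-1.65), Mgat4a (-1.53), Clec3b (-1.41), Tmem252 (-1.39), Gpat3 (-1.33) and Il2rg (-1.26). RT1-CE2 and RT1-T24.1, class I histocompatibility genes, were lower at -2.54 and -2.52, but belong to a family of near-identical genes, so their counts are uncertain. Inflammatory cytokines and adhesion genes were lower in 22 of 23 members, 3 past the test over all genes and 12 adjusted over the list alone (median -0.58, camera adjusted p = 3.21e-09). The adjusted p was 0.919 with an estimated correlation, and the list was called when either CON library was set alone. Il6 fell from 479 and 511 CPM to 255, Selp, the adhesion molecule P-selectin, from 1276 and 1464 to 712, and Cxcl2, at 12.9% of its level over all cells, from 69.5 and 74.9 to 35.1. Oxidative stress response genes were lower in 15 of 21 members, 1 past the test over all genes and 4 adjusted over the list alone (median -0.12, camera adjusted p = 0.0117, and 0.919 as adjusted p with an estimated correlation), among them Txnrd1, which reduces thioredoxin, at -0.94. Of the 87 calls in endothelial-like cells 6 held with DESeq2 size factors, of the genes named for these cells those of Gpm6a, Ncam1 and Chodl alone, and these lost the call with no cell filter, with each library clustered alone and with the highest doublet scores removed, where 2, 2 and 1 of the calls held. With the DESeq2 test 39 held, but not those of Cxcl2, H1f0, RT1-T24.1, Rpgr and Sdc2.

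The nitric oxide and cGMP pathway relaxes the smooth muscle of this tissue. Nos3, the endothelial nitric oxide synthase, was 149.6 CPM in endothelial-like cells of CNIED against 197 and 178 in CON (log2 fold -0.33, SE 0.18, edgeR adjusted p = 0.54). In smooth muscle-like cells Pde5a, which breaks down cGMP, was 45.7 against 51.4 and 53.6 (edgeR adjusted p = 0.908), and Gucy1a1, a subunit of the nitric oxide receptor, 212 against 199.6 and 208 (edgeR adjusted p = 0.97). In pericyte-like cells the log2 folds were -0.25 for Pde5a and 0.17 for Gucy1a1, neither called. Nos3 was 3.94 CPM against 12.4 and 2.14 in smooth muscle-like cells (log2 fold -1.02) and 6.52 against 17.3 and 6.48 in pericyte-like cells (-0.92). In endothelial-like cells Gucy1a1 was 87.7 CPM against 69.8 and 45.9 (log2 fold 0.59, edgeR adjusted p = 0.308), and Pde5a 3.99 against 6.85 and 5.15 (-0.61). The list of this pathway was not called in any of the 7 classes by camera, with a lowest adjusted p of 0.145 in Schwann-like cells. Prkg1 was not analysed here.

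In smooth muscle-like cells, Tgfb3 and the cytoskeletal actin Actb were higher in CNIED, and Apold1, Thbd and Cxcl1 were lower. Tgfb3, a TGF-beta ligand, rose from 68.7 and 60.3 CPM to 132 (log2 fold 1.03, SE 0.16, edgeR adjusted p = 0.0176), and Actb from 5012 and 5604 to 9339. Apold1 fell from 654 and 693 to 256 (log2 fold -1.39, edgeR adjusted p = 0.00242), and Thbd, the anticoagulant thrombomodulin, by 1.45 on the log2 scale. Cxcl1 fell from 1021 and 932 to 467 (log2 fold -1.06, edgeR adjusted p = 0.0112). Thbd and Cxcl1 stood in this class at 25.9% and 40.5% of their level over all kept cells, where their log2 folds were -1.53 and -1.32.

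Hey1, a target of Notch, and Il1r1, the receptor of interleukin 1, were lower in smooth muscle-like cells at -1.11 and -1.25, as were Spry4 (38.6 CPM against 78.1 and 76.1), Arhgdib (log2 fold -0.94) and Procr (-0.88). Cilp and Ppp1r1b were higher at 0.98 and 0.93, the latter at 29.7% of its level over all kept cells, where its log2 fold was 1.37. Myoc, Ucma and Gpx3, at 1.77, 1.04 and 0.88, stood at 11%, 15.7% and 11.8% of their level over all kept cells, where they were higher in CNIED by 1.44, 0.80 and 0.90. TGF-beta signalling genes were higher in 18 of 26 members, 1 past the test over all genes and 6 adjusted over the list alone (median 0.24, camera adjusted p = 6.39e-06, and 0.919 as adjusted p with an estimated correlation). Contractile genes were higher in 18 of 22 members, 0 of them adjusted over the list alone, with a median of 0.10 (0.20 and 0.07 against CON replicates 1 and 2, with the CON libraries -0.10 apart; camera adjusted p = 0.031, and 0.919 as adjusted p with an estimated correlation). Acta2, smooth muscle actin, was 11495 CPM against 9065 and 9468 (edgeR adjusted p = 0.524). Inflammatory cytokines and adhesion genes were lower in 17 of 23 members, 2 past the test over all genes and 5 adjusted over the list alone (median -0.43, camera adjusted p = 7.07e-07, and 0.919 as adjusted p with an estimated correlation), at a median of 31.5% of their level over all cells with 9 members under 20%. Endothelial markers summed to 310.5 against 439 and 376 CPM of the unscaled total in the class. Of the 41 calls in smooth muscle-like cells 18 held with DESeq2 size factors, but not those of Hey1, Il1r1, Spry4, Arhgdib, Procr, Cilp, Ppp1r1b, Ucma and Gpx3. With the DESeq2 test 15 held, but not those of Tgfb3, Myoc, Hey1, Il1r1, Spry4, Cilp, Ppp1r1b and Ucma. Of the calls 7 held at resolution 2.0, but not those of Tgfb3, Actb, Apold1, Thbd and Cxcl1.

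In pericyte-like cells, the chemokine Ccl19 and the opioid precursor Penk were higher in CNIED, and Il13ra2, a receptor of interleukin 13, was lower. Ccl19 rose from 23.8 and 41.1 CPM to 129 (log2 fold 2.02, SE 0.25, edgeR adjusted p = 0.0128), and Penk from 17.1 and 20.3 to 59.9. Il13ra2 fell from 107 and 103 to 19.5 (log2 fold -2.43, SE 0.23, edgeR adjusted p = 0.00183). Adamts9, a metalloprotease, fell by 1.56 on the log2 scale, Akap12, a scaffold protein, by 1.52 and Nop14 by 1.51. Igfbp3 and Myoc were higher at 1.77 and 1.72, with 20.2% and 10.4% of their level over all cells. Fibrillar collagen and elastic matrix genes were higher in 18 of 24 members, 0 past the test over all genes and 4 adjusted over the list alone (median 0.18, camera adjusted p = 0.000595, and 0.919 as adjusted p with an estimated correlation). The median member stood at 70.7% of its level over all cells, and fibroblast markers in pericyte-like cells summed to 30686 against 24580 and 27700 CPM of the unscaled total. Over all kept cells these markers summed to 61890 in CNIED against 54603 and 73370 in CON replicates 1 and 2. Eln, which encodes elastin, was 298 CPM against 176 and 161, and Col12a1 69.5 against 34.1 and 22.2, neither called. Class II histocompatibility genes, which present antigen, were lower in 5 of 5 members, 5 adjusted over the list alone (median -2.61, camera adjusted p = 5.19e-12, and 0.919 as adjusted p with an estimated correlation), at a median of 3.46% of their level over all cells. Cd74, their invariant chain, was 3.48 CPM against 19.4 and 21.7 and was not called. Of the 14 calls in pericyte-like cells 9 held with DESeq2 size factors, but not that of Igfbp3, and 9 with the DESeq2 test, but not those of Igfbp3 and Penk. Of these calls 0 held at resolution 2.0, with each library clustered alone 0, and with a stricter cell filter 2, of the named genes that of Il13ra2 alone. With the highest doublet scores removed Penk turned to a log2 fold of -0.88 and lost the call.

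In Schwann-like cells of CNIED, myelin genes were lower, and matrix and TGF-beta genes were higher. All 17 tested myelin genes were lower, 0 past the test over all genes and 11 adjusted over the list alone (median log2 fold -0.63, camera adjusted p = 3.06e-07). The adjusted p was 0.919 with an estimated correlation, and the list was also called when CON replicate 2 was set alone. Prx, which encodes the myelin protein periaxin, was 672 CPM against 979.9 and 1134 (edgeR adjusted p = 0.311). Cluster 22, which is led by Mbp and other myelin genes, was 26.1% of the class in CNIED against 46.3% and 44% in CON, and cluster 15, led by Scn7a, held the rest.

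Fibrillar collagen and elastic matrix genes were higher in 17 of 22 members in Schwann-like cells, 3 past the test over all genes and 4 adjusted over the list alone (median 0.38, camera adjusted p = 2.09e-07), and TGF-beta signalling genes in 19 of 27, 4 past the test and 8 adjusted over the list alone (median 0.50, camera adjusted p = 1.83e-07). For both lists the adjusted p was 0.919 with an estimated correlation, and both were also called when CON replicate 2 was set alone. Their median members stood at 29.1% and 46.7% of their level over all kept cells. Fibroblast markers in Schwann-like cells summed to 19760 CPM of the unscaled total in CNIED against 12308 and 14716 in CON. Over all kept cells these markers lay between the CON libraries, at 61890 in CNIED against 54603 and 73370 in CON replicates 1 and 2. Dcn, a proteoglycan of connective tissue, rose from 977 and 1216 CPM to 2945, and Ccn2, a matricellular protein, from 179 and 165 to 410.2, at 15.8% and 28.9% of their level over all cells. Lamc3, Gpx3 and Thbs1 were higher at 2.16, 1.89 and 1.81, at 19.2%, 17.2% and 19.6% of that level, and Manba, a lysosomal mannosidase, at 1.86 and 154%. Selp fell by 3.54 on the log2 scale (SE 0.47, edgeR adjusted p = 0.00264) at 39.6% of its level over all cells, where its log2 fold was -2.01, and endothelial markers summed to 151 against 478 and 248 CPM in the class. Cacna1c, a calcium channel subunit, fell by 1.97, Fgf1, a growth factor, by 1.94, and Apod by 1.82 at 8.2% of its level over all cells. Genes of smooth muscle contraction were lower in 17 of 21 members, 1 past the test over all genes and 9 adjusted over the list alone (median -0.78, camera adjusted p = 3.22e-07, and 0.919 as adjusted p with an estimated correlation), at a median of 27.9% of their level over all cells. Smooth muscle markers summed to 285 against 705 and 577 CPM in the class. Of the 54 calls in Schwann-like cells 54 held with DESeq2 size factors and 5 with the DESeq2 test, which kept those of Dcn, Gpx3 and Selp among the named genes. With each library clustered alone 2 held and with equal cells per library 4, of the named genes those of Gpx3 under both and Selp under the latter.

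In macrophage-like cells, immediate early genes were higher in CNIED as a list, and resident macrophage genes were lower. Of 25 tested genes of dissociation and immediate early response 21 were higher, 0 past the test over all genes and 7 adjusted over the list alone (median log2 fold 0.56, camera adjusted p = 1.7e-07). The adjusted p was 0.919 with an estimated correlation, and the list was called when either CON library was set alone. Fos was 5692 CPM against 2728 and 2333, and Jun 2598 against 1284 and 1172 (edgeR adjusted p = 0.408 for each). Resident macrophage genes were lower in 11 of 13 members, 3 adjusted over the list alone, with a median of -0.83 (-0.33 and -1.26 against CON replicates 1 and 2, with the CON libraries -0.69 apart; camera adjusted p = 1.61e-05, and 0.919 as adjusted p with an estimated correlation). Cd163, the haemoglobin scavenger receptor, was 249 CPM against 638 and 1329.8, Il10, an anti-inflammatory cytokine, 139 against 360.0 and 658, and Mmp12, macrophage elastase, 53 against 16.8 and 6.25.

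In lymphatic endothelial-like cells, a pair of haemoglobin genes was among the 3 called genes, and inflammatory genes were lower in CNIED as a list. The haemoglobin genes Hba.a2 and Hbb.b1, chosen after their values were seen, were higher at 2.91 and 3.22. With the highest doublet scores removed both lost the call and turned, to log2 folds of -0.58 and -0.64. They were also called higher in smooth muscle-like cells, at 3.39 and 3.83, and there too lost the call with the highest doublet scores removed (-0.16 and 0.22). Haemoglobin in total was 889.8 CPM of this class in CNIED against 128 and 92.2 in CON, 558 CPM against 19.9 and 93.7 in smooth muscle-like and 34.8 CPM against 44.3 and 1409 in pericyte-like cells, but over all kept cells 198 against 41.5 and 633. Inflammatory cytokines and adhesion genes were lower in 17 of 21 members, 0 past the test over all genes and 6 adjusted over the list alone (median -0.43, camera adjusted p = 2.37e-07, and 0.919 as adjusted p with an estimated correlation), at a median of 47.1% of their level over all cells. Cxcl10, a chemokine induced by interferon, was 52.4 CPM against 177 and 154, and Tnfaip3, an inhibitor of NF-kB, 105 against 248 and 264, neither called.

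**Figure D3:**
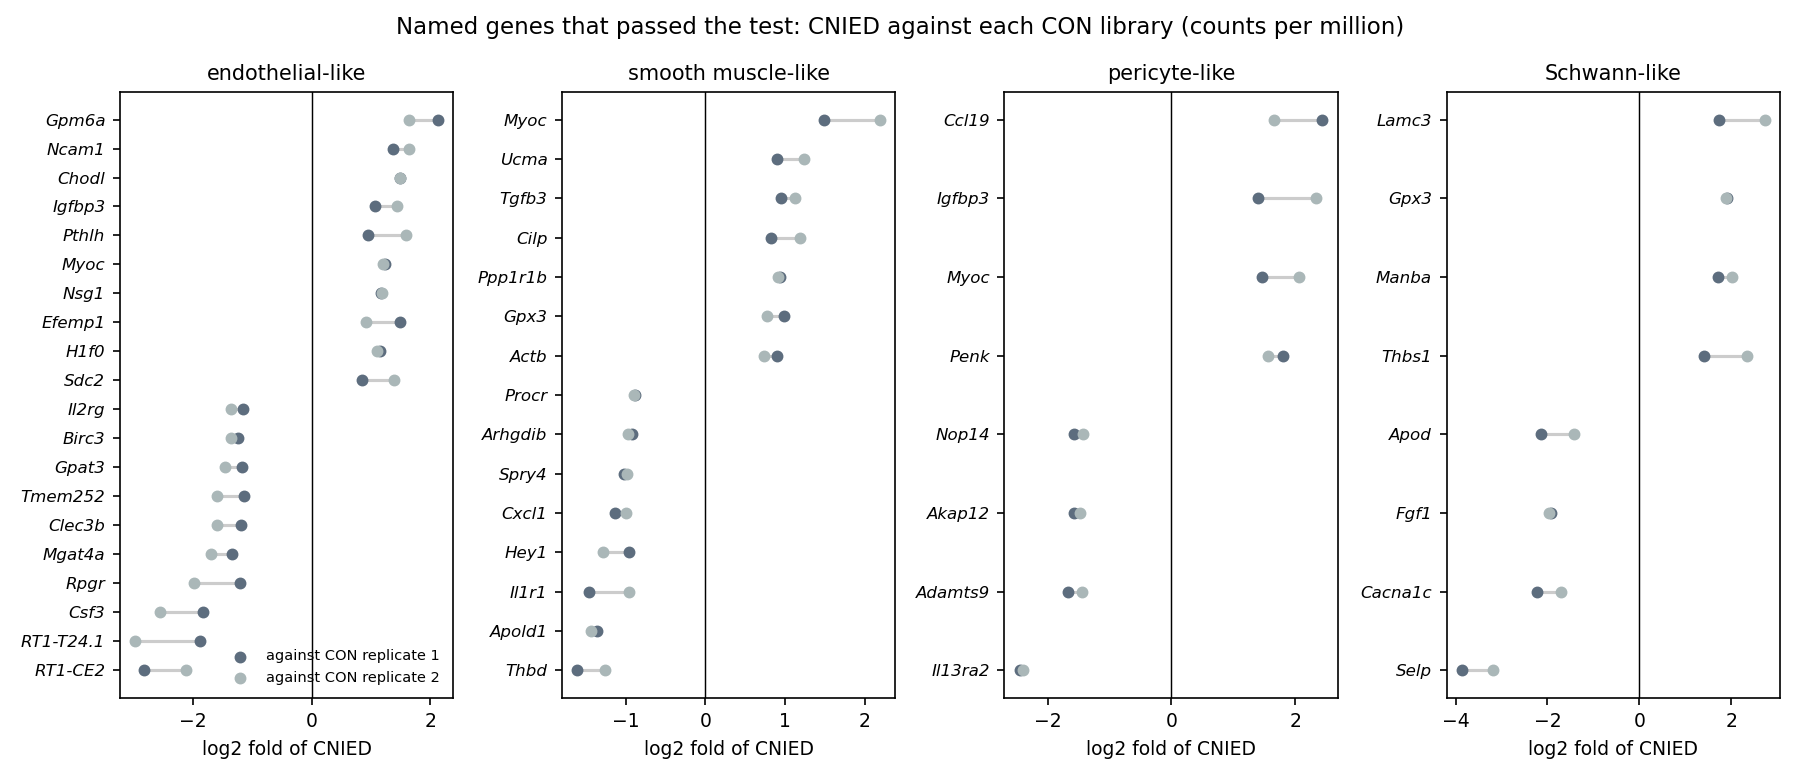
Log2 fold of CNIED (horizontal axis) against each CON library, from CPM, for the genes named by the size of their fold that passed the test (vertical axis), in endothelial-like, smooth muscle-like, pericyte-like and Schwann-like cells; points are CON replicates 1 and 2. Both points of each gene lie on the same side of 0 because the naming rule required it.

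Further lists were called at the preset correlation and had an adjusted p of 0.919 with an estimated correlation. Where leaving out a CON library moved a median by over 1.5 times, the medians against CON replicates 1 and 2 follow it in that order. Genes of synthetic smooth muscle, the state of muscle cells that make matrix, were higher in pericyte-like, Schwann-like and smooth muscle-like cells (median log2 folds 0.32 with 0.38 and 0.18, 0.43 and 0.37), and basement membrane genes in Schwann-like cells (0.21). Oxidative phosphorylation genes were higher in smooth muscle-like (0.14, 0.21 and 0.07) and lymphatic endothelial-like cells (0.17), and myofibroblast genes in pericyte-like cells (0.18, -0.04 and 0.39, with the CON libraries 0.42 apart). Class II histocompatibility genes were lower in smooth muscle-like (-1.65) and fibroblast-like cells (-1.71, -0.86 and -0.80), at 2.74% and 2.81% of their level over all cells. Endothelial identity genes were lower in pericyte-like (-0.78, -1.02 and -0.39), macrophage-like (-0.75, -1.23 and -0.64), fibroblast-like (-0.68, -0.88 and -0.15), Schwann-like (-0.66, -0.94 and -0.13) and smooth muscle-like (-0.63, -0.70 and -0.02) cells, at 32.1%, 30.2%, 22.1%, 57.7% and 23.1% of their level over all cells, and were not called in endothelial-like cells (-0.09). Interferon response genes were lower in Schwann-like cells (-0.50), as were steroid hormone response genes (-0.39, -0.14 and -0.61). In lymphatic endothelial-like cells, genes of Schwann cell repair (-0.67, -0.78 and -0.42), apoptosis and p53 (-0.34) and inflammatory and lipid-laden macrophages (-0.40, -0.13 and -0.63) were lower. Genes of inflammatory cytokines and adhesion were also lower in Schwann-like (-0.56) and macrophage-like cells (-0.50, -0.33 and -0.66), and genes of inflammatory and lipid-laden macrophages in fibroblast-like cells (-0.84, -0.61 and -0.12). TGF-beta signalling genes were higher in macrophage-like (0.41, 0.23 and 0.64) and endothelial-like cells (0.17, 0.12 and 0.26), and fibrillar collagen and elastic matrix genes in macrophage-like cells (0.41, 0.13 and 0.71) at 12.2% of their level over all cells. Adventitial progenitor genes were lower in endothelial-like (-0.61, -0.69 and -0.32) and lymphatic endothelial-like cells (-0.52), contractile genes lower in the latter (-0.53, -0.71 and -0.13) and higher in pericyte-like cells (0.11, -0.12 and 0.38). In smooth muscle-like cells interferon response (-0.40, -0.52 and -0.17) and myelin genes (-0.18) were lower, as were myelin genes in fibroblast-like cells (-0.26, -0.17 and -0.16). Median members stood at 31.6% of their level over all cells for inflammatory cytokines and adhesion in Schwann-like cells, 34.1% for lipid-laden macrophages in fibroblast-like, 33.7% for TGF-beta signalling in macrophage-like and 33% for contractile genes in lymphatic endothelial-like cells, and at 33.2% for interferon response and 22.7% for myelin in smooth muscle-like cells. Cell cycle, neurotrophic and axon guidance, and hypoxia and glycolysis genes were not called in any class, with lowest adjusted p-values by camera of 0.263, 0.149 and 0.137. Nuclear RNA genes had under 5 tested members in each class and were not tested.

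Genes held in a class at a low level relative to all kept cells moved with the whole library. A low relative level does not show that the RNA of a gene came from other cells. In the classes outside the stromal clusters, genes held at under 20% of their level over all cells had slopes on the fold of the whole library of 0.801 to 1.45 and Pearson correlations of 0.725 to 0.85 across genes, which are not independent replicates. Genes held at over 200% had slopes of 0.0777 to 0.425. Of the called genes, 12 in endothelial-like, 12 in smooth muscle-like, 1 in pericyte-like and 17 in Schwann-like cells were held at under 20%, and each had the direction of the whole library. Comp, a cartilage matrix protein that leads clusters 1 and 5, was 129 CPM in endothelial-like cells of CNIED against 64 and 45.9 in CON, and 147 against 48 and 31.9 in macrophage-like cells.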

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

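Both results here were found by a rule for opposite directions, and the tests in this part were chosen after the results were seen. Genes of dissociation and immediate early response had a median log2 fold of 0.565 in macrophage-like and 0.195 in smooth muscle-like cells but -0.201 in lymphatic endothelial-like cells, and CNIED moved that way against each CON library. Fibrillar collagen and elastic matrix genes had a median of 0.38 in Schwann-like and 0.18 in pericyte-like cells but -0.153 in fibroblast-like cells. With an estimated correlation none of these list tests was called, and the differences between classes were not tested.

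Genes of the stromal clusters were higher in other classes of CNIED. There were 31 calls held at under 20% of the level over all cells and higher in CNIED. A gene called in several classes, such as Myoc, counts once for each. Over these calls the median of class minus library log2 fold was 0.28 (interval over resampled calls 0.117 to 0.627). The interval treats repeats of a gene as separate, and 100% of the calls had the direction of the library. The calls were chosen for being higher in the class, which favours a positive difference and a shared direction. Free RNA from a library with more stromal cells may account for these genes. The interval reaches past the bound of 0.5, set after the values were seen, so this explanation stays open. That nerve injury raised these genes in the cells themselves cannot be told apart from it with 1 CNIED library.

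Myelin genes were lower in Schwann-like cells of CNIED. A smaller share of the myelinating cluster 22 and lower expression in the myelinating cells after nerve injury cannot be told apart, since 7 of the 10 leading genes of cluster 22 are in the list and a cell that lost them would leave the cluster. With the same number of cells per cluster in each library the median log2 fold was -0.016 against -0.645 with all cells, and 35.3% of the list was lower within cluster 22 (median 0.044), but clusters formed by the list's own genes fix both values. Cluster 15 had a median of -0.712 with 13 of 13 members lower, which stays open too.

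Stromal clusters took a larger share of CNIED, with a ratio of 1.34 to the mean of CON for all of them, and 1.32 with each library clustered alone, where those kept out of the fibroblast-like class had a ratio of 0.923. A like gain of every stromal cluster, as from better release of all stromal cells, was not settled. Clusters 12 and 18, 2 of 8 whose leading genes did not change, lay farther from both CON libraries than a set distance. That distance was the largest ratio between the CON libraries in any stromal cluster (2.43 times). They held 3.8% and 0.647% of stromal cells in CNIED, 10.1% and 2.4% in CON replicate 1 and 11.6% and 1.94% in CON replicate 2. With either CON library set alone, by a distance set from the remaining libraries, 0 did. In the joint clustering these 2 clusters thus did not share the gain. Of all kept cells, too, clusters 12 and 18 took smaller shares of CNIED, 3.08% and 0.525%. They took 5.84% and 1.38% of CON replicate 1 and 7.4% and 1.24% of CON replicate 2. By a range of CON widened by 1.5 times, 4 of 12 clusters lay outside, against 0 and 3 with CON replicates 1 and 2 set alone, which left the question open. The wider distance was chosen after those values were seen and rests on 1 CNIED library, so it cannot decide. A tissue piece with more of the layer that holds clusters 0, 1 and 5 stays open too. Among cells outside the stromal clusters, 0 of 6 other classes lay beyond 1.5 times the mean of CON (ratios 0.732 to 1.36). Against single CON libraries some did: Schwann-like cells at 1.81 times replicate 1, smooth muscle-like at 1.65 and lymphatic endothelial-like at 0.655 times replicate 2. Such proportions do not tell this explanation from the others, and no value that tells the layers apart was at hand. A tissue piece of this kind and a change of the tissue after nerve injury cannot be told apart with 1 CNIED library. Release that differs between stromal clusters was not tested.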

How the results depend on the processing

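No paired analysis was possible because CNIED has 1 library. The removal of the highest doublet scores and equal cells per cluster were chosen after the results were seen, and without a CON library values have no test. The ratio of shares to the mean of CON kept its direction in 6 of 7 classes under each setting tried, though with each library clustered alone the pericyte-like share was 3.36% in CNIED and 2.86% in CON replicate 1. The ratio of fibroblast-like shares reversed, to 1.08 at resolution 0.5 and 1.49 with each library clustered alone, and that of pericyte-like shares moved to 0.447 at resolution 2.0 and 0.718 with each library clustered alone. The ratio for stromal clusters kept out of the fibroblast-like class, 2.34 as reported, reversed to 0.923 with each library clustered alone. It moved to 2.91 with a stricter cell filter, 2.72 with doublets kept and 2.96 at resolution 0.5. The ratio for all stromal clusters, 1.34 as reported, was 1.32 to 1.38 under the settings tried. Its moves were smaller than the spread between its values against CON replicates 1 and 2. Numbers of changed genes moved by over 1.5 times, or from or to 0, as follows, and the cause was not tested. With a stricter cell filter there were 19 in fibroblast-like, 14 in endothelial-like, 2 in pericyte-like, 138 in Schwann-like and 53 in lymphatic endothelial-like cells. With no cell filter the counts were 13 in fibroblast-like, 2 in endothelial-like, 19 in smooth muscle-like, 9 in pericyte-like, 159 in Schwann-like and 45 in lymphatic endothelial-like cells. Keeping doublets added 1 cell, after which clusters were formed anew. With doublets kept the counts were 123 in fibroblast-like, 16 in smooth muscle-like and 8 in pericyte-like cells. With resolution 0.5 there were 62 in fibroblast-like, 24 in endothelial-like and 59 in macrophage-like cells. With resolution 2.0 the counts were 15 in fibroblast-like, 7 in smooth muscle-like, 0 in pericyte-like, 241 in Schwann-like, 7 in macrophage-like and 12 in lymphatic endothelial-like cells. With each library clustered alone the counts were 344 in fibroblast-like, 2 in endothelial-like, 0 in pericyte-like, 2 in Schwann-like, 12 in macrophage-like and 30 in lymphatic endothelial-like cells. With the highest doublet scores removed there were 31 in fibroblast-like, 1 in endothelial-like and 22 in pericyte-like cells. With DESeq2 size factors the counts were 11 in fibroblast-like, 6 in endothelial-like, 18 in smooth muscle-like and 9 in pericyte-like cells. With the DESeq2 test the counts were 120 in fibroblast-like, 43 in endothelial-like, 16 in smooth muscle-like, 9 in pericyte-like, 5 in Schwann-like, 2 in macrophage-like and 6 in lymphatic endothelial-like cells. With no count filter there were 689 in fibroblast-like, 452 in endothelial-like, 259 in smooth muscle-like, 200 in pericyte-like, 216 in Schwann-like, 244 in macrophage-like and 170 in lymphatic endothelial-like cells. With equal cells per library the counts were 0 in fibroblast-like, 208 in smooth muscle-like, 157 in pericyte-like, 4 in Schwann-like and 2 in macrophage-like cells. With equal totals per library the counts were 125 in fibroblast-like, 222 in endothelial-like, 165 in smooth muscle-like, 8 in pericyte-like, 147 in Schwann-like, 11 in macrophage-like and 132 in lymphatic endothelial-like cells. With equal cells per cluster there were 14 in fibroblast-like, 173 in endothelial-like, 172 in smooth muscle-like, 111 in pericyte-like, 6 in Schwann-like and 95 in macrophage-like cells. Without either CON library, each called gene kept its direction, but the genes were called on these same libraries, so this is no independent check. Of 64 named genes that were called, 33 lost the call with DESeq2 size factors and 26 with the DESeq2 test. With an estimated correlation 0 list tests were called, and those called at the preset correlation had a camera adjusted p of 0.919. On 1 residual degree of freedom that version could hardly call a list. With DESeq2 size factors 56 list tests were called. Without CON replicates 1 and 2 in turn, medians in pericyte-like cells were 0.386 and -0.0449 for myofibroblast activation and 0.382 and -0.123 for smooth muscle contractile genes. Without CON replicates 1 and 2 in turn, 20 and 15 list medians moved by more than the spread of CON. With the highest doublet scores removed, called genes kept their direction in 50 of 54 in Schwann-like, 40 of 41 in smooth muscle-like, 13 of 14 in pericyte-like and 1 of 3 in lymphatic endothelial-like cells. In simulated counts 18 to 52 of 100 genes changed 2-fold were recovered at 945205 UMIs in lymphatic endothelial-like cells of CNIED and 3 to 26 at 28174634 in fibroblast-like cells, so recovery did not follow depth between these classes.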

Other observations

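The tests by cluster number in this part, the genes named from them and Comp were chosen after the data were seen, while the calls of Myoc and Selp across classes come from planned tests. Within stromal clusters 0, 1 and 5, tested by number because they were kept out of the fibroblast-like class, matrix genes were lower in CNIED and Igfbp5 was higher. The edgeR test called 68, 65 and 57 genes in these clusters, of which 9, 12 and 7 were higher. These gene tests were run under the main setting only, so whether their calls hold under other settings is not known. Sparc, which binds collagen, fell in each (log2 folds -1.25, -1.12 and -1.21). Col1a1, the main fibrillar collagen, fell in clusters 1 and 5 (-1.25 and -1.46), and Col3a1 in clusters 0 and 5 (-1.35 and -0.99). Igfbp5, which binds insulin-like growth factors, rose in each (0.99, 1.52 and 1.19), as did the sulfotransferase Chst5 (2.18, 2.21 and 2.35). Comp rose in cluster 0 (1.65).

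Fibrillar collagen and elastic matrix genes were lower in 18 of 24 members in each of the clusters, 3, 4 and 6 of them past the test in clusters 0, 1 and 5 (medians -0.32, -0.44 and -0.41). Inflammatory cytokines and adhesion genes had medians of -0.58, -0.24 and -0.70. Both lists were called in each cluster by camera over 99 list and cluster tests, and had an adjusted p of 0.86 with an estimated correlation. Here too that version rests on 1 residual degree of freedom and could hardly call a list. Endothelial identity genes were also called lower in clusters 0, 1 and 5 (medians -0.85, -0.89 and -0.93) and class II histocompatibility genes in clusters 0 and 1 (-2.40 and -2.37), with the same adjusted p with an estimated correlation. Endothelial markers summed to 57.6 against 157 and 95.6 CPM of the unscaled total in cluster 0, 75.7 against 194 and 125 in cluster 1 and 109 against 287 and 149 in cluster 5. Across classes, Myoc and Comp, both among the leading genes of stromal clusters 1 and 5, were higher in several: Myoc was called higher in 4 (log2 folds 1.22 to 1.77), Comp in 3 and Selp lower in 3 (-3.54 to -0.94), and with DESeq2 size factors Myoc and Selp lost the call in endothelial-like cells.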
